A study of Xenopus tropicalis with 6 samples.

How the data were processed

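RNA-seq libraries from whole Xenopus tropicalis (western clawed frog) embryos at blastula stage 9 were analysed. Per the labels' protocols, one-cell embryos received Morpholinos, which are modified antisense oligonucleotides, here of the kind that covers a start codon and blocks translation. The total was 60 ng per embryo in both groups, as 30 ng against tet2 plus 30 ng against tet3 or as 60 ng of a standard control Morpholino, in 5 nl. Each library came from 50 embryos and was made with a stranded, poly(A)-selecting kit, per the labels' protocols.

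The deposited values are whole-number read counts per gene model, with 1 file per library and no header. The submitters' processing notes name bcl2fastq, FastQC, STAR 2.5.4b, SAMtools 1.3.1, Subread and featureCounts 1.5.1, without stating the role or order of each. The genome build, the annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Overlapping, antisense and near-identical genes may therefore share or lose reads. Each file holds the same 28165 identifiers, of the form Xetro followed by a letter and a number, and no unassigned-read rows. Of these, 8293 had no count in any library.

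The files do not pair these identifiers with gene names, and 0 of the 28165 matched the RefSeq gene table of assembly UCB_Xtro_10.0 used for names. Names, positions and functions of the genes are therefore not given. The levels of tet2 and tet3 and the 17 gene lists fixed in advance (germ layer, maternal, RNA polymerase III, DNA methylation, stress and other genes) were not analysed here. A translation-blocking Morpholino need not lower its target mRNA, so those levels would not have measured the knockdown.

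Groups were taken from the sample titles. The main test was edgeR 4.0.16 (R 4.3.3): filterByExpr with its default minimum count of 10, TMM (trimmed mean of M values) factors, and glmQLFit with glmQLFTest on group alone over all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. The filter kept 13221 genes, which held at least 99.95% of the counts of every library. Fold changes are Tet2/Tet3 Morpholino over control Morpholino. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Levels are CPM, read counts scaled to a library total of 1000000 with TMM factors.

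Same-numbered libraries were checked for pairing before the fits were compared. The log2 CPM deviations from the group means correlated across genes at 0.87, 0.87 and 0.74 for replicates 1, 2 and 3. All differently numbered combinations of a control and a Tet2/Tet3 library lay between -0.70 and -0.16. Deviations from a group mean cancel out within the group. These negative values therefore follow largely from the positive same-numbered ones and are not separate evidence. With all 3 pairs above 0.1, the numbers were taken to pair the libraries. The labels do not say what the pairs share. The fit with the replicate number as a block, set as an alternative before the data were examined, is therefore reported beside the main fit. Libraries of 1 group differed by far more than counting noise, with chi-square per degree of freedom from 25.4 to 99.2, so none was counted as a duplicate. The labels call the samples biological triplicates.

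The rule for named genes asked for called genes whose groups did not overlap, with a mean of at least 1 CPM in the higher group, ranked by fold change. It also asked for a gene symbol. As no identifier has one, it was applied without that condition and limited to the 2 largest falls and the 2 largest rises.

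The alternatives set before the data were examined were size factors of the RLE type as in DESeq2, upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, edgeR's glmTreat against a 1.2-fold minimum, the replicate block, and leaving out each library in turn. The counts of 2-fold changes and the alternatives run on the blocked fit were chosen after seeing the data.

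The procedure was tested on simulated data. In 10 simulations of the Tet2/Tet3 against control comparison over 13221 genes, counts were drawn with the real means, depths, pair differences and blocked dispersions, and 200 genes were changed. With group alone, 25.7% of the 2-fold and 1.3% of the 1.5-fold changes were recovered, and 0% of calls were false. With the replicate block, 90.0% and 72.2% were recovered, and 12.1% of calls were false, above the nominal 5%. Median estimates lay between 0.996 and 1.00 times the simulated log2 fold change in both designs. The real fits called 1518 genes with group alone and 6247 with the block, far more than the 200 changed here. The cut-off set by the p adjustment therefore differs, and neither the recovered nor the false shares carry over to the real fits.

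Libraries held 37973110 to 44792849 counts, so a level of 1 CPM stood for 38.0 to 44.8 reads before TMM scaling. Single quantities were compared with exact two-sided permutation tests, for which 3 libraries against 3 cannot give a p below 0.1. Figures were drawn with matplotlib 3.10.9.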

Results

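The data were 6 poly(A) RNA-seq libraries of Xenopus tropicalis blastulae at stage 9, a stage soon after the embryo begins to transcribe its own genome. Embryos carried either a control Morpholino (3 libraries) or Morpholinos against tet2 and tet3 (3 libraries). The TET proteins are dioxygenases that oxidise 5-methylcytosine in DNA. The design poses 1 question, which is how the blastula transcriptome differs when translation of both tet mRNAs is targeted. Control libraries held 43718155, 44792849 and 39044871 counts for replicates 1, 2 and 3, and Tet2/Tet3 libraries 41876179, 40352849 and 37973110. The deposited identifiers carry no gene names, so genes are described by number, direction, size and abundance, and 4 by identifier.

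Libraries with the same replicate number resembled each other more than libraries of the same treatment. Control and Tet2/Tet3 libraries of the same number correlated at r = 0.988, 0.984 and 0.985 over log2 CPM of the 13221 tested genes, which are not independent replicates. Within the control group r was 0.956 to 0.979, and within the Tet2/Tet3 group 0.954 to 0.976. The first principal component took 55.1% of the variance and ordered the replicate numbers, with replicate 1 lowest and replicate 2 highest in both groups. Each Tet2/Tet3 library scored higher than its same-numbered control on the second component (20.6%), by 36.2, 44.9 and 49.9 in pairs 1, 2 and 3. On the first component it also scored higher, by 17.5, 25.8 and 12.2.

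**Figure D1:**
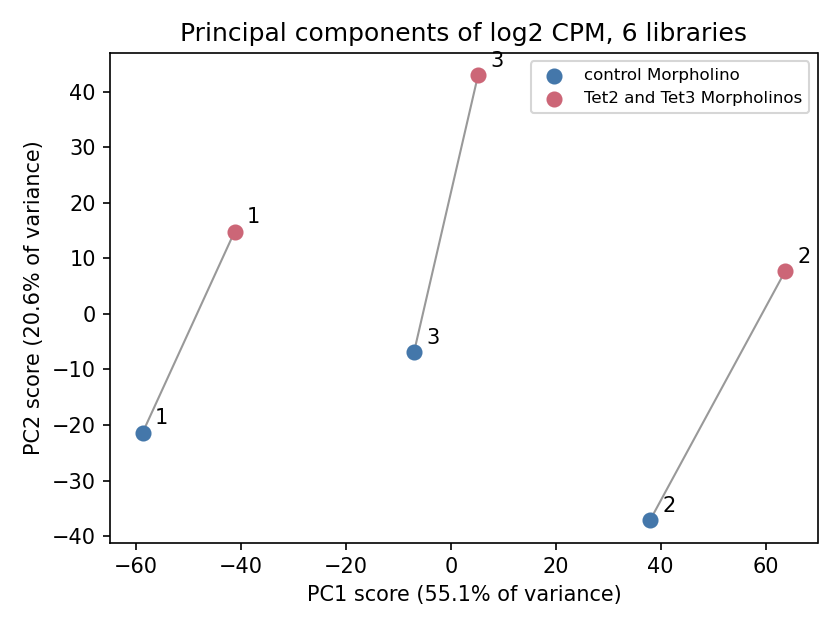
Scores of the 6 libraries on the first (x axis, 55.1% of variance) and second (y axis, 20.6%) principal components of log2 CPM. Numbers are replicate numbers and grey lines join the control (blue) and Tet2/Tet3 (red) library of each number; replicate numbers part along x, and every red point lies above and to the right of its blue partner.

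In Tet2/Tet3 Morpholino embryos, deep falls outnumbered deep rises, and most rises were shallow. Of 13221 tested genes, 724 fell and 794 rose at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg, n = 3 per group). Together these 1518 genes were 11.5% of those tested. The falls had a median of 1.75-fold (log2 -0.81, interquartile range -1.20 to -0.58). The rises had a median of 1.41-fold (log2 0.50, interquartile range 0.41 to 0.61). The called genes differed in abundance, as 515 of the rises and 140 of the falls had a mean of 100 CPM or more. Smaller changes can be called in abundant genes, so the medians do not compare like sets. At least 2-fold changes numbered 258 falls and 12 rises, and at least 4-fold changes 44 falls and 0 rises. Leaving out control replicate 1, 2 or 3 gave 144, 126 or 79 falls and 13, 10 or 4 rises of at least 2-fold, and leaving out Tet2/Tet3 replicate 1, 2 or 3 gave 449, 157 or 76 falls and 28, 11 or 5 rises. These are 11.1 (without control replicate 1) to 19.8 falls per rise, against 21.5 with all libraries. Fold changes are relative to the bulk of the genes, and a constant log2 shift of 0.20 in favour of the Tet2/Tet3 group would bring falls of at least 2-fold under 2 per such rise, counted over all 9608 genes with a mean of at least 5 CPM, called or not. At 4-fold or more, the same 9608 genes hold 35 falls and 1 rise, and 25 and 2 after that shift. A shift of 0.79 would bring falls of at least 4-fold under 2 per such rise as well.

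With the replicate number as a block, 3149 genes fell and 3098 rose, or 47.3% of those tested. These 6247 genes included all 1518 of the fit without the block, each in the same direction. All 1518 already had the same direction in all 3 pairs, so the shared direction is not separate evidence. The common biological coefficient of variation was 0.276 without the block and 0.071 with it. Most blocked calls were small: 1938 of the falls and 2670 of the rises were under 1.5-fold. The asymmetry in size remained but was smaller, with 428 falls and 36 rises of at least 2-fold (11.9 falls per rise), and 49 and 1 of at least 4-fold. Without replicate 1, the blocked fit gave 510 falls and 79 rises of at least 2-fold, or 6.46 falls per rise. With the block, the filter of 1 CPM gave 357 and 19 (18.8 per rise), and DESeq2 364 and 22. In simulations with 200 changed genes, 12.1% of blocked calls were false, above the nominal 5%. As the real blocked fit called many more genes, its own share of false calls is not known. The count without the block depended on single libraries: leaving out control replicate 1, 2 or 3 gave 394, 249 or 111 called genes, and leaving out Tet2/Tet3 replicate 1, 2 or 3 gave 2651, 403 or 110. Rises were 52.3% of the calls with all libraries, and 41.9%, 29.3%, 18.02%, 50.1%, 39.5% and 22.7% in those 6 fits.

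**Figure D2:**
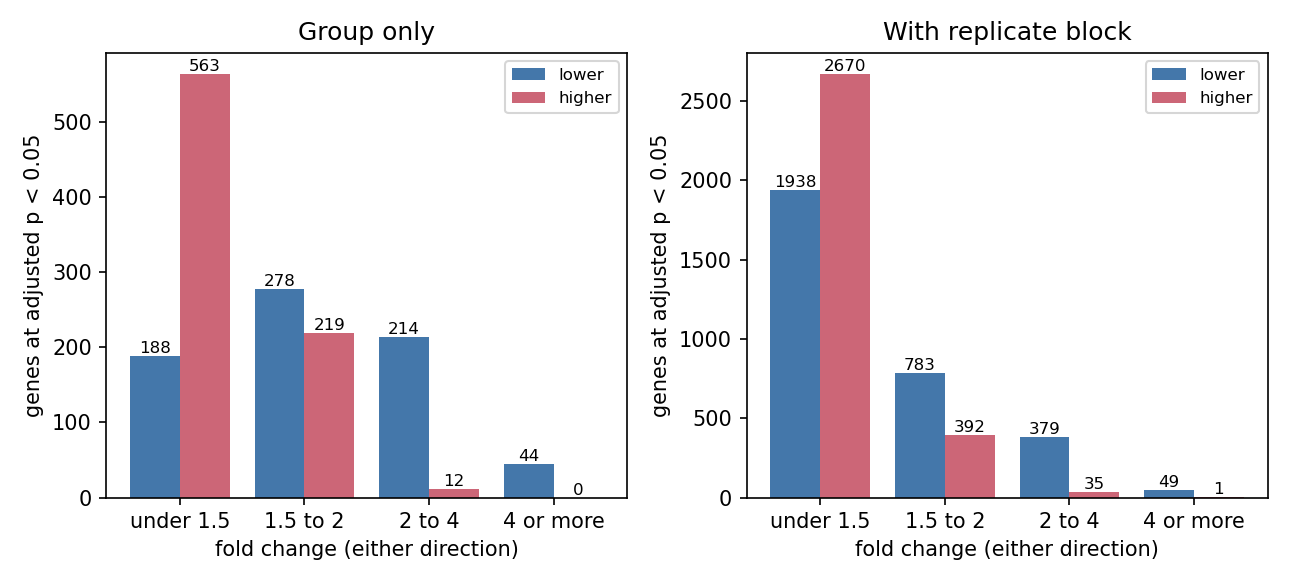
Number of genes at an adjusted p under 0.05 (y axis; scales differ between panels) by size of fold change (x axis), without (left) and with (right) the replicate block; blue bars are genes lower and red bars genes higher in Tet2/Tet3 embryos. Rises outnumber falls under 1.5-fold (563 against 188 on the left), and falls outnumber rises from 2 to 4-fold (214 against 12 on the left).

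The largest fall was in Xetro.K00110, which went from 48.5 ± 7.6 CPM in control to 1.26 ± 0.65 CPM in Tet2/Tet3 libraries (mean ± SD, n = 3). The log2 fold change was -5.27 (SE 0.45, adjusted p = 0.0027, edgeR), a 38.5-fold fall. Its raw counts were 2624, 2000 and 1842 in the controls and 21, 63 and 58 in the Tet2/Tet3 libraries. Xetro.B00454 fell 19.2-fold, from 155.9 ± 17.4 to 8.11 ± 1.27 CPM (n = 3), with a log2 fold change of -4.26 (SE 0.16, adjusted p = 0.00021, edgeR). Across the 3 pairs its fall ranged from 16.7 to 23.2-fold.

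The largest rise was in Xetro.K00850, from 4.22 ± 2.47 to 16.7 ± 2.66 CPM (n = 3), with a log2 fold change of 1.98 (SE 0.40, adjusted p = 0.029, edgeR). Its rise ranged from 1.93 to 6.83-fold across the pairs. Leaving out control replicate 2 or 3 or Tet2/Tet3 replicate 2 or 3 ended this call, with adjusted p from 0.089 to 0.122. Xetro.A03096 rose 2.75-fold, from 60.6 ± 8.2 to 166.5 ± 12.7 CPM (n = 3), with a log2 fold change of 1.46 (SE 0.12, adjusted p = 0.0026, edgeR). With the replicate block, the adjusted p was 1.2e-05 for Xetro.K00110, 3.1e-07 for Xetro.B00454, 0.0012 for Xetro.K00850 and 1.3e-05 for Xetro.A03096.

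**Figure D3:**
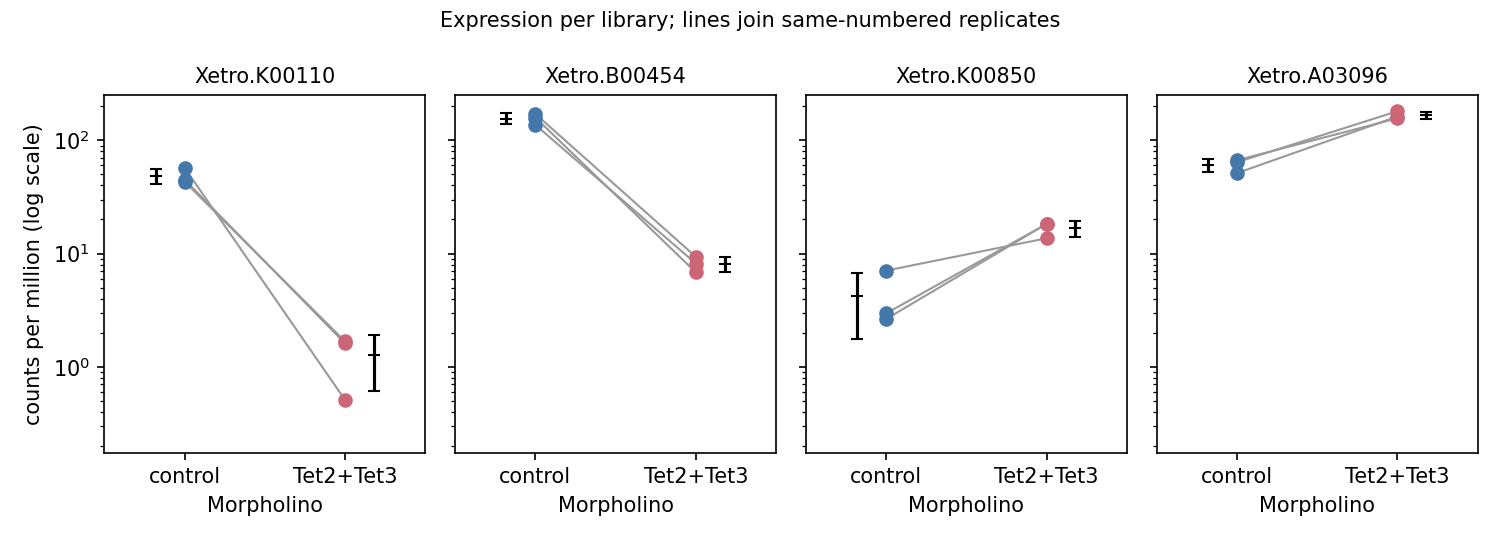
Expression of the 4 named identifiers in CPM (y axis, log scale) in control (blue) and Tet2/Tet3 (red) libraries; points are libraries, grey lines join same-numbered replicates, and black bars are the mean ± SD of 3 libraries. Xetro.K00110 and Xetro.B00454 lie lower and Xetro.K00850 and Xetro.A03096 higher in every Tet2/Tet3 library than in every control, which the rule for naming genes required.

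Direction went with abundance. Classes were set by the mean of all libraries of both groups, so a gene's own change enters its class. The numbers called also depend on how small a change can be called in a class. The class medians cover called and uncalled genes and do not depend on this. Among the 2900 genes with a mean of 100 CPM or more, 515 rose and 140 fell, and the median log2 fold change of all 2900 was 0.15. Among the 5628 genes of 10 to 100 CPM, 257 rose and 442 fell. Among the 2981 genes of 1 to 10 CPM, 21 rose and 130 fell, with a median log2 fold change over all of them of -0.10. In the 1712 genes under 1 CPM, 1 rose and 12 fell. The median of the most abundant class was 0.11, 0.18 and 0.15 in pairs 1, 2 and 3, and 0.15 and 0.16 with RLE and upper-quartile factors. The median of the 1 to 10 CPM class was -0.10, -0.14 and -0.10 in the 3 pairs. With the replicate block, 1420 genes rose and 525 fell in the class of 100 CPM or more, and 302 rose and 745 fell in the class of 1 to 10 CPM.

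The Tet2/Tet3 libraries were also more concentrated in their most abundant transcripts. The top 100 genes of each library took 15.7 ± 0.5% of its counts in Tet2/Tet3 embryos and 13.1 ± 0.05% in controls (mean ± SD, n = 3, exact two-sided permutation p = 0.1, the smallest this design allows). The top 10 genes took 3.45 ± 0.20% and 2.59 ± 0.04% (exact permutation p = 0.1). Both shares were higher in Tet2/Tet3 libraries in 3 of 3 pairs, with an exact two-sided p of 0.25 each when signs were flipped within pairs, the smallest that 3 pairs allow. The genes called lower held 6.09 ± 0.17% of control counts and 3.28 ± 0.33% of Tet2/Tet3 counts. The genes called higher held 19.2 ± 0.04% and 25.0 ± 0.6%. These last shares describe genes chosen for their change and were not tested.

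The change was shared across the 3 pairs. The log2 difference between the Tet2/Tet3 and control library of a pair correlated across genes at r = 0.64 for pairs 1 and 2, 0.66 for pairs 1 and 3, and 0.69 for pairs 2 and 3. Genes are not independent replicates, so these values carry no p. The 3 pairs had the same direction for 9111 genes (68.9%), where chance gives 25% on average. Genes vary together, so this share can lie far from 25% without a group difference, and it was not tested. For 4374 genes (33.1%), all 3 Tet2/Tet3 libraries lay on 1 side of all 3 controls, where chance gives 10% for exchangeable libraries. As these libraries are paired, that value does not apply as such. The other 9 splits of the 6 libraries gave 1.06% to 22.5%, and the 3 of them that part all pairs 1.06% to 1.57%. Each of those splits has both groups on both sides, so a real group difference would itself lower their values. They are therefore no chance level, and the excess over chance was not sized. Of the 4374 genes, 2171 were higher and 2203 lower. No gene with 10 or more counts in each library of 1 group had 0 counts throughout the other group.

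Fewer genes had at least 1 count in the Tet2/Tet3 libraries. The number was 16632 ± 257 against 17077 ± 327 in controls (mean ± SD, n = 3), lower in 3 of 3 pairs. The differences within pairs 1, 2 and 3 were -560, -504 and -271 genes (mean -445, SD 153, n = 3 pairs). The exact two-sided permutation p was 0.3 between the groups and 0.25 when signs were flipped within pairs, the smallest p that 3 pairs allow. Total counts were also lower in the Tet2/Tet3 library of each pair, and with libraries thinned to an equal total times TMM factor the mean difference was -248 genes (SD 144).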

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

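The scalings and filters moved the counts least: with RLE factors, upper-quartile factors, no filter and the filter of 1 CPM in 3 libraries, the number of called genes was 1516, 1530, 1158 and 1655 against 1518. The median log2 fold change of all tested genes lay between -0.017 and 0.005 under these 4. DESeq2 called 2965 genes (1593 higher, 1372 lower), and the cause of the larger count was not tested. Against a 1.2-fold minimum (glmTreat), 430 were called (142 higher, 288 lower, 7 of the higher by at least 2-fold). The replicate block gave 6247 (3098 higher and 3149 lower, of which 36 and 428 by at least 2-fold), and it ended none of the calls made without it. Leaving out 1 library at a time, which breaks a pair, gave 110 to 2651 called genes, 20 to 1328 higher and 85 to 1323 lower; rises were 18.02% to 50.1% of these calls, against 52.3%. At 2-fold or more it gave 4 to 28 higher and 76 to 449 lower, against 12 and 258. The highest values came without Tet2/Tet3 replicate 1. With the block, leaving out a pair gave 43 to 79 rises of at least 2-fold against 36. DESeq2 with the block gave 22, and the filter of 1 CPM with the block 19; the causes were not tested. The other blocked counts stayed within 1.5 times their value in all 8 alternatives. Xetro.K00110, Xetro.B00454 and Xetro.A03096 stayed called in the same direction in all 12 alternatives run on them, and Xetro.K00850 in 8. The analyses of tet2, tet3 and the gene lists were not run, because no gene names were paired with the identifiers. Depth limits the rare genes: 6651 of the 19872 identifiers with a count were too low to test, and of the 1712 tested genes under 1 CPM, 1 was called higher and 12 lower.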

Other observations

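The tests in this part on low counts, on a constant scaling error, on effective library depth and on neighbouring identifiers, except the one by abundance class, were chosen after the result was seen. The others were set down before their own outcome was seen, though some concern patterns already seen by then, such as the counts of 2-fold changes.

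Falls were deeper than rises, with 21.5 called falls of 2-fold or more per such rise, 11.9 with the replicate block (6.46 without pair 1), and 11.1 to 19.8 with 1 library left out (11.1 without control replicate 1, 12.6 without control replicate 2, 14.3 without Tet2/Tet3 replicate 2). Low counts do not account for the whole of this, as the ratio was 26.0 (78 falls, 3 rises) among genes with a mean of at least 50 CPM. Such falls and rises numbered 12 and 1 under 1 CPM and 65 and 1 at 1 to 10 CPM. They were 153 and 7 at 10 to 100 CPM, and 28 and 3 at 100 CPM or more, where falls per rise were fewest. No 1 pair carried the asymmetry. Among all 9608 genes of at least 5 CPM, called or not, the lowest ratio of any pair was 8.68 (321 falls and 37 rises in pair 3). A constant scaling error between the groups stays open at 2-fold, where a log2 shift of 0.20 would bring the ratio among those 9608 genes from 17.5 to under 2, and the 3 scalings, whose medians differ by only 0.011, cannot test it. That shift would leave 12.5 falls per rise at 4-fold or more among the same 9608 genes (25 and 2, from 35 and 1). A shift of 0.79 would bring this ratio under 2 as well. Nothing in the data sets the size of such an error, so it stays open at 4-fold too. A shift along the axis that separates the replicate numbers stays open as a hypothesis. Each Tet2/Tet3 library lay higher on the first component than its partner. Across genes, a pair's effect was correlated with the difference of the other 2 pairs' means. The r was 0.077 for pair 3 (pair 2 minus 1), 0.17 for pair 2 (pair 3 minus 1) and -0.13 for pair 1 (pair 3 minus 2). Replicate 3 lay below replicate 2 on the first component, so all 3 signs go with a shift up that component, though the values are small. The signs come from the same libraries as the component scores and are not separate evidence. All 3 values missed the size set in advance for this cause, and not all were under the size set against it. Whether such a shift would make falls deeper than rises was not tested. The knockdown itself was not tested as an explanation.

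The number of calls was set against the other splits of the 6 libraries into 3 and 3. Of the 10 splits, 1, the real one, called 1518 genes (794 higher, 724 lower), and the highest of the other 9 was 0 by edgeR. At an unadjusted p under 0.05 the highest of those was 2401 genes against 3718, and by DESeq2 366 against 2965. With the replicate block, 4 splits part all 3 pairs; the real one called 6247 genes, and the highest of the other 3 was 0 by edgeR and 0 by DESeq2, with 65 genes at an unadjusted p under 0.05 against 7189. Neither 10 nor 4 splits can give a share under 0.05. Every other split also has both groups on both sides, so a real group difference would add to the spread and lower its count. The counts of the other splits are therefore no rate of false calls.

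Fewer genes had a count in the Tet2/Tet3 libraries, with a mean difference of -445 genes. Thinned to the 37973110 counts of the smallest library, the mean difference was -364 genes (-489, -367 and -235 in pairs 1, 2 and 3; exact two-sided permutation p = 0.2 between the groups, n = 3). In these 6 libraries the total count was therefore not the whole source of the difference. The permutation ignores the pairing, and its p does not part the remaining difference from the spread between libraries. Thinned to an equal total times TMM factor, which also allows for the larger share of the most abundant genes, the mean difference was -248 genes (-398, -234 and -111, SD 144), so that the depth left for the other genes stays open as a cause. No biological explanation was tested.

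Called genes were looked at by the number in their identifier, on the hypothesis that identifiers close in number change together. Among tested identifiers of the same letter series, 68 pairs of neighbouring identifiers were both called higher. Random placements of the calls within each series gave a mean of 48.3 (10000 placements, adjusted permutation p = 0.0042 over 2 tests). Placing calls within classes of abundance as well gave a mean of 49.9 (permutation p = 0.006, not adjusted). This argues against sharing a class of abundance as the whole cause. The classes are wide, so likeness in abundance within a class was not matched and stays open. For genes called lower the number was 48, against a mean of 39.6 (adjusted permutation p = 0.096). What the numbering follows is not given in the sources used here, so reads shared between neighbouring copies and true co-regulation both stay open.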
